A study of Homo sapiens with 3 samples.

How the data were processed

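Gene expression was measured with Applied Biosystems 1-colour chemiluminescent arrays in 3 samples of HCT116, an established human colorectal carcinoma line in which hPTTG1 (securin) had been knocked out. Per the labels' protocols, cells were transfected by lipofection with the empty vector or with an hPTTG1 expression vector, selected in hygromycin and lysed in Trizol. There was 1 vector control and 2 hPTTG1-transfected samples, which the labels call different transfected cells. Per the headers, the arrays are named pchyg (control), 7-2 (transfected 1) and 18-2 (transfected 2), and what these names mean is not stated. Nothing states that they were separate cultures of one line. The p-values therefore measure only the spread between these samples, which may hold differences between the transfected cells or be technical. Per the labels' protocols, cRNA was made by reverse transcription and in vitro transcription and labelled with digoxigenin, although the label field names biotin.

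Each array had 37842 spots, of which 32878 were gene probes. Per the file headers, each spot has a signal, its standard deviation, a signal-to-noise score, a flag and an assay normalized signal. The deposited signal is a linear spot intensity that had not been normalized between arrays. The values show that background had been subtracted before deposit. On gene probes with a signal-to-noise score under 1 the deposited signal equals the spot's own standard deviation, so such values are a floor and have no order. The assay normalized signal is a deposited intensity that the scanner software divided by a factor close to the array's median signal. The deposited series table equals that column on 32878 of 32878 probes on each array, to within 0.006, so its scale and direction are known; its medians were 1.09, 1.11 and 1.08 for the control, transfected 1 and transfected 2. It was not centred per gene. The scanner software, its version and the meaning of the deposited flags are not given in the sources used here.

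Gene probes with a flag of at least 5000 on any array were left out, which removed 373. The signal was put on the log2 scale and quantile normalized over the remaining gene probes with limma 3.58.1 in R 4.3.3. Of several probes of a gene, the probe with the highest mean was used. This left 28578 genes, of which 17376 had a signal-to-noise score of at least 3, here called detected, on at least 1 array and were tested. The comparison of control and transfected samples used limma's lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. With 1 control the spread came from the transfected samples alone, with 1 residual degree of freedom and 2.03 prior degrees of freedom. The control was therefore assumed to vary like the transfected samples. Beside this test, genes at least 2-fold apart from the control in the same direction in both transfected samples were counted, among genes detected in the control or in both transfected samples. Errors are the SD of the log2 values of the transfected samples (n = 2) or limma's SE. Where a gene was not detected in one group, the fold is called estimated. It is not a bound, because the undetected signal is itself uncertain. It sets the detected group's mean against, per array, the higher of the lowest normalized signal of detected genes and the gene's own value. The number of arrays limits the precision.

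The files identify genes by Celera hCG numbers, by RefSeq accessions or by other identifiers. Through a RefSeq gene table of assembly GRCh38.p14, 129 probes were named by accession and 13 by an hCG synonym, for 129 symbols. The other 32736 probes kept their identifiers, and no coordinates were used. Of the 12 genes that were to be reported whatever their values, PTTG1 first among them, 0 were among those symbols. Of the 428 members of 19 gene lists, 1 was named, ANAPC1. The PTTG1 level, the list medians and the set tests were therefore not analysed here. The named genes are the 12 highest and 12 lowest genes with a symbol, ranked by the smaller of both samples' differences from the control, that lay on the same side of the control in both and were detected in both transfected samples or in the control, plus members of the lists. The groups, the tests, this rule, the lists and all but 2 of the alternative settings below were fixed before the data were examined.

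The alternatives were array medians, the scanner's normalized signal, an added offset of 786 signal units (the 5th percentile of detected signals), flagged spots kept, the mean over a gene's probes, detection on all 3 arrays, no filter on dim probes, limma's trended and robust eBayes, other thresholds and leaving out each transfected sample. The 2 exceptions, scaling by the 75th percentile and by hybridization control spots, were added after the data were seen. Both tests were tested on simulated arrays with 200 changed genes. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.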

Results

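Expression was compared between hPTTG1-null HCT116 colorectal cancer cells carrying an empty vector (n = 1) and cells of the same background stably transfected with hPTTG1 (n = 2). hPTTG1 encodes securin, the inhibitor of separase that is destroyed at the onset of anaphase. The comparison asks which transcripts differ once hPTTG1 is put back. On the control array 17121 of 32878 gene probes were detected (52.1%), against 16355 (49.7%) and 16676 (50.7%) in transfected samples 1 and 2. The level of hPTTG1 itself, which would check the labels, was not analysed here because no probe could be assigned to it.

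Among the genes with a symbol that were detected on all 3 arrays, AHNAK2, a large scaffold protein gene, was farthest above the control, at 4.09-fold (log2 difference 2.03, SE 0.26; SD 0.14, n = 2). CNTNAP3, a contactin-associated cell adhesion gene, was 2.57-fold higher (1.36, SE 0.24), and GTF2IRD2, which encodes a transcription factor of the TFII-I family, was 2.20-fold higher. PML, the scaffold of PML nuclear bodies, was detected in both transfected samples and not in the control. It was an estimated 3.15-fold higher (4.31-fold in sample 1 and 2.30-fold in sample 2). CENPX, a kinetochore and Fanconi pathway gene, was the lowest of the genes with a symbol that were detected on all 3 arrays, at 2.59-fold lower (log2 difference -1.37, SE 0.25; SD 0.12, n = 2). Scaled to the hybridization control spots, AHNAK2, CNTNAP3 and GTF2IRD2 had log2 differences of 1.70, 1.04 and 0.86, in place of 2.03, 1.36 and 1.14. CENPX then had a log2 difference of -1.78.

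MZB1, LRRC45 and KLC2 were detected in the control alone. MZB1, an endoplasmic reticulum chaperone gene of B cells, was an estimated 3.17-fold lower. LRRC45, a centrosomal linker gene, was an estimated 2.72-fold lower, and KLC2, a kinesin light chain gene, an estimated 2.79-fold lower. With an offset added to all signals, the log2 differences of MZB1, LRRC45, KLC2 and PML shrank from -1.66, -1.44, -1.48 and 1.65 to -0.58, -0.88, -0.52 and 0.92. MZB1, LRRC45, KLC2 and PML belong to the genes not detected on all 3 arrays. Among such genes, setting the control against both other samples gave 607 genes at least 2-fold apart, while setting apart transfected sample 1 gave 573 and transfected sample 2 gave 640. Detection itself depends on the change, so these counts do not decide whether the differences are noise.

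In limma's test none of these genes passed. The adjusted p in limma was 0.411 for AHNAK2, CNTNAP3, GTF2IRD2, CENPX, MZB1 and LRRC45, 0.42 for KLC2 and 0.47 for PML. When limma was run only on the 12848 genes detected on all 3 arrays, 4 of the 54 genes with a symbol passed: AHNAK2 (adjusted p = 0.0118), CNTNAP3 (0.0269), CENPX (0.0274) and GTF2IRD2 (0.0437). The test takes its spread from the transfected samples alone. Over these 12848 genes, the variance particular to 1 sample, worked out from the pairwise differences, was 0.205 for the control. It was 0.057 for transfected sample 1 and 0.061 for sample 2. The control's value would also hold any effect of hPTTG1, so whether the control varies like the other samples is not settled. CNTNAP3 and GTF2IRD2 have near-identical copies in the genome, whose transcripts the probes may not separate.

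**Figure D1:**
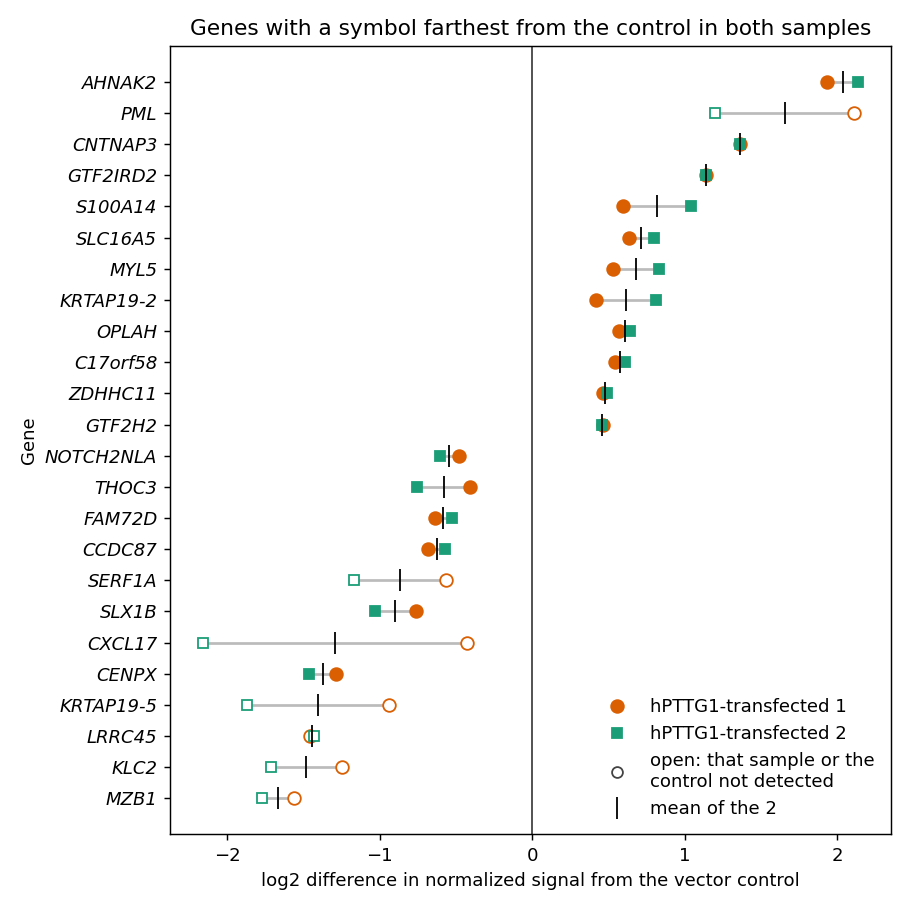
Log2 difference in normalized signal from the vector control (x axis) for the 12 highest and 12 lowest genes with a symbol (y axis), with a circle for transfected sample 1, a square for sample 2 and a bar for their mean; open symbols mark values for which that sample or the control was not detected. Among genes with filled symbols AHNAK2 lies highest at a mean of 2.03 and CENPX lowest at -1.37.

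Smaller differences were seen in genes of several kinds. S100A14, which encodes a calcium-binding S100 protein, was 1.76-fold higher, and SLC16A5, a monocarboxylate transporter gene, 1.64-fold higher. MYL5, a myosin light chain gene, was 1.60-fold higher, the oxoprolinase gene OPLAH 1.52-fold, C17orf58 1.49-fold, ZDHHC11 1.39-fold and the TFIIH subunit gene GTF2H2 1.38-fold. Scaled to the hybridization control spots, these 7 genes lay between 0.08 (GTF2H2) and 0.44 (S100A14) on the log2 scale, in place of 0.46 to 0.82. SLX1B, a structure-specific endonuclease gene, was 1.86-fold lower, with both of its probes lower (log2 difference -0.90, and -0.62 as their mean). CCDC87 was 1.54-fold and NOTCH2NLA 1.46-fold lower, and FAM72D and the mRNA export gene THOC3 both had a log2 difference of -0.58. Of the 2 probes of NOTCH2NLA, which before normalization differed by -0.84 and -0.36, the brighter was used, and their mean gave -0.31 in place of -0.54. The same scaling took SLX1B, CCDC87, FAM72D, THOC3 and NOTCH2NLA farther from the control, to between -0.87 (NOTCH2NLA) and -1.26 (SLX1B). SLX1B, FAM72D, NOTCH2NLA, GTF2H2 and SERF1A also have near-identical copies.

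The chemokine gene CXCL17 was detected in the control alone and was an estimated 2.44-fold lower (log2 difference -1.29, and -0.46 with the offset). Its estimated fold was 1.35 in sample 1 and 4.41 in sample 2. SERF1A, also detected in the control alone, was an estimated 1.82-fold lower. Of the keratin-associated protein genes, KRTAP19-2 was 1.53-fold higher. KRTAP19-5, detected in the control alone, was an estimated 2.65-fold lower (log2 difference -1.40, and -0.89 with the offset). Neither these genes nor those of the smaller differences above passed limma's test, with adjusted p between 0.469 (SLX1B) and 0.663 (CXCL17).

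The gene lists could be followed through 1 member. ANAPC1, a subunit of the ubiquitin ligase that marks securin for degradation, was 1.24-fold higher (log2 difference 0.31, SE 0.33; SD 0.34, n = 2), which did not pass limma's test (adjusted p = 0.765). Its 3 probes did not move together: before normalization their log2 differences were 0.02, 0.00 and -0.72. Scaling to the hybridization control spots turned its sign (-0.021), and the mean over its probes gave 0.07.

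Across all 17376 genes, limma called 0 genes at an adjusted p of 0.05, with a smallest adjusted p of 0.411. At an unadjusted p of 0.05 there were 1818 genes, 761 higher and 1057 lower in the transfected samples. limma called 376 genes among those detected on all 3 arrays (154 higher and 222 lower), and 1325 genes with a trended, robust variance. Both calls included 344 genes, but both used the same arrays and the same control, so this overlap is not independent evidence. The control added no spread of its own, and limma drew each gene's spread partly from that of other genes. The called genes in both fits therefore rest on that fitted spread as well as on their own. In simulated arrays with the fitted spread, limma recovered 0 of 100 genes changed 2-fold and 0 of 100 changed 4-fold over all genes. Over the genes detected on all 3 arrays it recovered 6 of 100 and 96 of 100. With an SD of 0.1 for every gene it recovered 100 of 100 at both sizes in both gene sets.

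By size, 1030 of 15596 genes lay at least 2-fold from the control in both transfected samples, 319 higher and 711 lower. The share that was higher was 31.0%, but 12.8% when arrays were scaled to the hybridization control spots (172 higher and 1177 lower), a scaling that put the median log2 difference of all genes at -0.31. It was 41.6% among genes detected on all 3 arrays (176 higher and 247 lower) and 43.2% with no filter on dim probes (766 higher and 1008 lower). Under the size rule a gene could enter through detection in the control alone, or else had to be detected in both transfected samples. That rule favours lower genes, so the balance of 319 and 711 is not a measure of lost expression. Simulated arrays with no change gave 581 genes past the size rule among the 15596. They gave 29 among the 12848 genes detected on all 3 arrays, where the observed number was 423. The simulation drew the control with the spread fitted to the transfected samples, alike for dim and bright genes. A control array with more spread could give more such genes without a change, so 29 is not a firm baseline for 423. Genes with a symbol made up 4 of the higher and 4 of the lower genes. The largest differences belonged to genes without a symbol. hCG22218 was an estimated 14.3-fold and hCG40845 an estimated 11.9-fold higher, neither being detected in the control. hCG1816863 was 62.8-fold lower in sample 1 and was not detected in sample 2, and hCG19444 was an estimated 15.0-fold lower.

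The spread within the transfected group was read from the comparison of its members. Of 17376 genes, 2036 were at least 2-fold apart between transfected samples 1 and 2, 1095 higher in sample 2 and 941 lower. The balance turned with hybridization control spots (874 higher and 1106 lower) and with the scanner's normalized signal (980 higher and 1006 lower). Among the 12848 genes detected on all 3 arrays the number was 164, against 724 and 740 between the control and samples 1 and 2. The SD of the log2 difference over these genes was 0.344 between the transfected samples, 0.512 between the control and sample 1, and 0.516 between the control and sample 2.

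Each of the 3 samples was also set against both others. The control gave 1030 genes at least 2-fold apart from both, transfected sample 1 gave 612 and sample 2 gave 691. For each of the 3, fewer genes were higher than lower in both others: 319 and 711, 223 and 389, and 187 and 504. Among genes detected on all 3 arrays the counts were 423, 39 and 51, of which 176, 28 and 29 were higher in both others. limma called 0 genes over all genes for each of the 3, with 1818, 824 and 893 genes at an unadjusted p of 0.05.

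**Figure D2:**
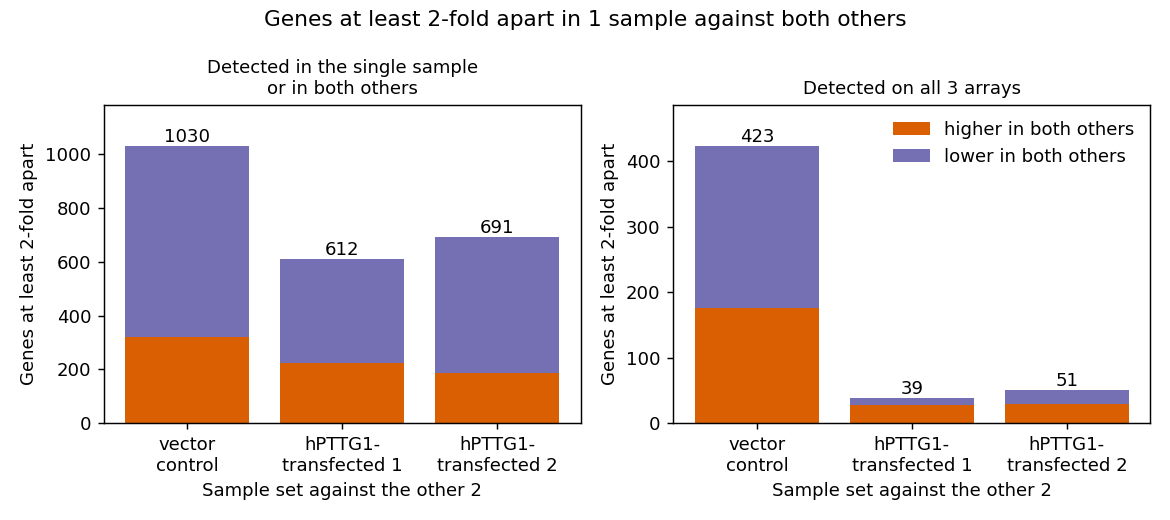
Number of genes at least 2-fold apart (y axis) when each sample (x axis) was set against both others, with orange for genes higher and purple for genes lower in both others. The left panel holds genes detected in the single sample or in both others (1030, 612 and 691 genes), the right panel genes detected on all 3 arrays (423, 39 and 51).

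Control spots differed between the arrays. The bacterial transcripts spiked into the in vitro transcription (BIOB, BIOC and BIOD, 119 spots) were 2.54-fold brighter on the control array than on that of transfected sample 1 (log2 difference -1.35, SD over spots 0.13) and 1.77-fold brighter than on that of sample 2 (-0.83, SD 0.15). The hybridization controls (234 spots) differed by 0.02 and 0.07 on the log2 scale. The spikes added before reverse transcription lay between: DAP differed by -0.27 and -0.40 (10 detected spots) and LYS by -0.46 and -0.62 (10 detected spots), and the 1 detected spot of PHE by -0.51 and -0.20.

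**Figure D3:**
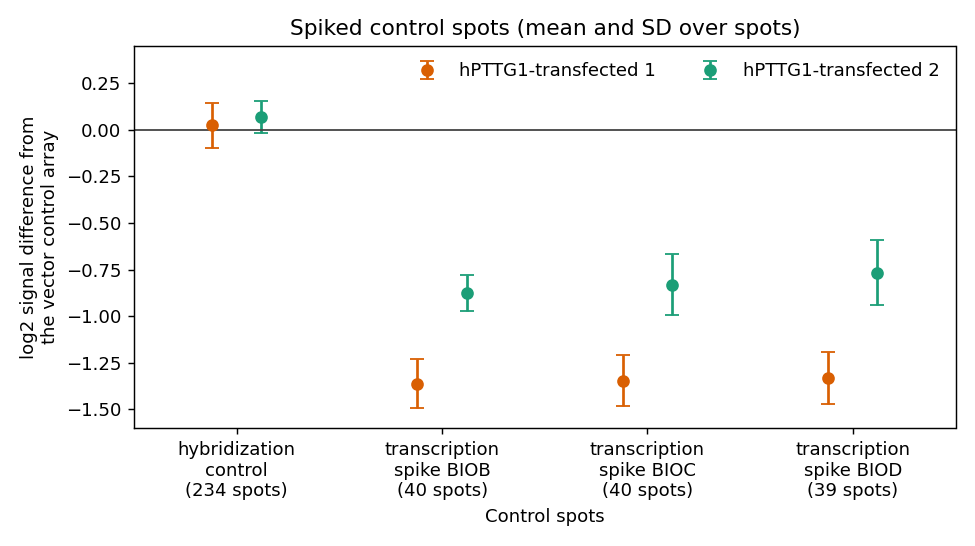
Log2 signal difference of each transfected array from the vector control array (y axis) for the hybridization controls and each transcription spike (x axis), with points for the mean and bars for the SD over spots. The hybridization controls lie near 0 (0.02 and 0.07), while all transcription spikes lie below it, at a mean of -1.35 in sample 1 and -0.83 in sample 2.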

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

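The scalings by the 75th percentile and by hybridization control spots were chosen after the results were seen. No paired analysis was possible because there was 1 control, so the groups share only 1 replicate number. The limma count of 0 stayed at 0 with array medians, the scanner's normalized signal, flagged spots kept, the mean over probes, no filter on dim probes, an adjusted p of 0.1 and both added scalings. It was 15 with the offset, 376 among genes detected on all 3 arrays, 1325 with trended and robust eBayes, and 1818 at an unadjusted p of 0.05; of the 15 genes, 10 were among the 376. These calls share the same arrays and control, so their overlap is not independent evidence. With detection on all 3 arrays the prior degrees of freedom were 7.02 in place of 2.03 and fewer genes were tested. The cause of the other changes was not tested. Genes at least 2-fold from the control in both samples (1030) ranged from 973 to 1349 under the scalings, kept flags and averaged probes. They numbered 2596 at 1.5-fold, 314 at 3-fold, 378 with the offset, 423 with detection on all 3 arrays and 1774 with no filter; leaving out a transfected sample, so that 1 sample had to differ, gave 2371 to 2453. Genes 2-fold apart between the transfected samples (2036) numbered 3938 at 1.5-fold, 853 at 3-fold, 260 with the offset, 164 with detection on all 3 arrays and 4063 with no filter. Of 243 values of named genes tested with limma under alternatives, 231 kept their direction and side of its threshold, 11 passed it (4 with detection on all 3 arrays, 7 with trended and robust eBayes), and ANAPC1 reversed to -0.021 with hybridization control spots. The 50 values without 1 transfected sample have no test, and their direction was fixed by the rule that chose most of these genes. Array medians and the scanner's signal put the median log2 difference of all genes at about -0.10. Alternatives for the PTTG1 level and the gene lists, camera included, were not run for lack of named members. Signal over background is 1 limit: 30.7% to 33.1% of gene probes per array were at the floor.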

Other observations

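Tests chosen only after results were seen were the comparison of hybridization controls, the comparison of distances from the control, and the divisions of genes by detection on all 3 arrays and by mean signal; the prediction for genes detected on all 3 arrays was set earlier, for the undivided pattern. The predictions on array position and on gene probes of the spikes' brightness were set before their values were seen.

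The genes named here were chosen after their values were seen. The cytoplasmic actin gene ACTG1 was 1.20-fold higher (adjusted p = 0.732 in limma), and the ligand gene WNT7B was 1.09-fold lower (0.873). Of 54 genes with a symbol that were detected on all 3 arrays, 16 lay within 0.25 of the control on the log2 scale in both transfected samples. Of 17 keratin-associated protein probes, 2 were detected on all 3 arrays, as was 1 of 7 defensin probes.

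The control stood farther from both transfected samples than these did from each other. The control gave 1030 genes at least 2-fold apart from both, and the highest of the other ways of setting 1 sample apart gave 691; 1 of the 3 ways gave as many as 1030, and 3 ways are too few for a share under 0.05. Noise of dim probes as the source was argued against for genes with a mean signal above the median of all tested genes, where the control gave 280 genes against 9 and 9, 31.1 times the higher of these (95% interval 16.2 to 68.8). At or below that median the ratio was 1.1 (0.99 to 1.22), which leaves noise open for dim genes. It was 8.29 (6.19 to 11.3) for genes detected on all 3 arrays and 0.95 (0.85 to 1.06) for the others, among them hCG22218, hCG1816863, MZB1, LRRC45, KLC2 and PML, but detection depends on the change itself, so these values decide nothing. A position effect confined to a few blocks of the array was argued against. Without the 6 of 24 blocks with the highest share, the ratio over all genes of the size rule was still 1.41 (1.26 to 1.59). A gradient or unevenness over the whole array was not tested. The intervals of all these ratios treat genes as independent and cover counting error only, with 1 array per sample. With 1 control sample, an effect of hPTTG1 and a chance difference of that selected line cannot be told apart, and a biological reading stays an untested hypothesis.

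The transcription spikes were brighter on the control array on every one of 119 spots, which are copies of 15 probes. A brighter array as a whole was argued against by the hybridization controls, which differed by at most 0.07 (95% intervals over spots from 0.008 to 0.081). Their 234 spots are copies of 3 probes, so these intervals cover only the spread between copies. A reaction that also shifted gene probes of that brightness was set to give a median of -0.8 or lower, and to be argued against above -0.4. The median of 1748 such gene probes was -0.35, with quartiles of -0.63 and -0.09, against -0.21 for all gene probes. The bootstrap interval of the median (-0.37 to -0.33) lies above -0.4, but it was computed after the median and quartiles had been seen, it treats probes as independent, and the quartiles span -0.4; a smaller shift of this kind stays open.

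A labelling difference that grows with the spike gap would place transfected sample 1 farther from the control. Over the 423 genes detected on all 3 arrays the median ratio of log2 distances, sample 1 over sample 2, was 0.996 (bootstrap 95% interval 0.97 to 1.01), and 206 genes were farther in sample 1. These genes were chosen for lying far from the control in both samples, and both distances share the control's value, so the ratio is drawn to 1 and decides nothing. A labelling difference of the control sample could be present whether or not it grows with the spike gap, and these values do not settle whether a different amount of spike was added.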
